A study of Homo sapiens with 2 samples.

How the data were processed

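HL60 cells given 250 nM AraC for 1 day were sorted by Pyronin Y into a low (PY-Lo) and a high (PY-Hi) fraction within the Hoechst G0/G1 gate, with 1 library per fraction made with 10x Genomics GEM-X 3' chemistry, per the labels' protocols. The libraries were processed with Cell Ranger on GRCh38, per the labels. The version, the annotation and whether intronic reads were counted are not given in the sources used here. The deposited values are whole-number UMI counts per gene and barcode in a filtered matrix of called barcodes, per the labels, and barcodes with high mitochondrial counts were present in it. The barcode and gene lists of both libraries were used. The PY-Hi matrix was not analysed here. Gene identifiers were the same 33538 in both lists, and 99.8% of them are in GENCODE release 29, from which positions were taken. Every symbol of the 31 gene lists was found.

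A barcode was kept with at least 500 genes and at most 15% of UMIs from mitochondrially encoded genes. Scrublet, as run in scanpy 1.11.5 with 30 principal components, called doublets, which were left in. Levels are CPM, the counts of a gene summed over kept cells and scaled to a common total, with exact Poisson intervals, and shares of cells have exact Clopper-Pearson intervals, both at 95% and both for counting error only. For shares of cells, spread and the comparison by total UMIs, each cell was thinned at random without replacement to 2000 UMIs, which left out 31 of 1434 kept cells. Some shares of cells are also given before thinning. Spread was (variance - mean) / mean squared over thinned cells, for genes with a mean of at least 0.2 UMI, and 0.25 or more was called variable. Multinomial cells with the same means gave the level from counting alone. The comparison by total UMIs set the upper 25% of thinned cells over the lower 25%, for genes with at least 200 thinned UMIs in both together, with exact conditional binomial intervals and 1.5-fold as the size named. A list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean level, with the list's own members left in the bins. Clusters came from counts scaled to 10000 per cell, log1p, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9). Leading genes are ordered by fold over other cells with 10 CPM added to both, among genes found in at least 25% of the cluster.

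On simulated counts the comparison by total UMIs recovered 200 of 200 genes changed 2-fold among 976, with 1 false call of 776. Each group was drawn there as 1 pooled sample without spread between cells. False calls may therefore be more frequent in real cells, which do vary. The spread recovered 194 of 200 genes given an excess of 0.5 among 1646, with 65 false calls of 1446.

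With 1 library no test was made and no p-value computed from cells. The 31 gene lists, and the filters, thresholds and rule for named genes of the main results, were fixed before the data were examined. The list of nuclear-retained RNAs and the mitochondrial ranges were chosen afterwards. The rule named the 10 genes with the highest count, the 3 highest members of each list and every cytarabine list member, the 20 most variable genes and the highest 2 of lists with a variable gene, the 12 highest and 12 lowest genes by total UMIs and the ends of lists with a gene past 1.5-fold, and 6 leading genes per cluster. Of the pairs and list ends, those of lists described in a sentence are printed. CDKN2A and MYC were always named. Some genes and 1 list that this rule covers are not printed. MKI67, MPO, CCDC26, MALAT1, NEAT1 and other genes given by cluster or mitochondrial range were named after their values were seen. Genes of the Y chromosome and XIST were left out. Alternatives were other cell filters, thinning depths, floors, splits, denominators, doublet removal and cluster settings. Thinning to 20000 UMIs and leaving out clusters were chosen after seeing the data. Sequences of 15 genes were aligned to mitochondrial transcripts with blastn 2.17.0. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.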

Results

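HL60, an established human promyelocytic leukaemia cell line, was exposed to 250 nM cytarabine (AraC), a nucleoside analogue that is built into DNA during replication, for 1 day. The cells were then stained with Hoechst, which binds DNA, and Pyronin Y, which binds RNA, and the Pyronin Y low (PY-Lo) and Pyronin Y high (PY-Hi) fractions of the cells gated as G0/G1 were sorted and each taken through 1 droplet-based 3' single-cell RNA library. The series title asks about fast transcription changes in resistance to this drug. The count matrix of the PY-Lo library was analysed, with 14377 barcodes, 33538 genes and 195414934 unique molecular identifiers (UMIs, each counting 1 captured transcript). UMIs per barcode ran from 501 to 143416 with a median of 7262. With 1 library there is no replicate error, so no test was made. The intervals are 95% exact intervals that cover counting error only.

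The comparison the sort implies is PY-Lo against PY-Hi, the cells with less against more RNA within one DNA content gate. The PY-Lo barcode list held 14377 barcodes and the PY-Hi list 14457, over the same 33538 genes. PY-Hi gene counts were not analysed here, so no gene is compared between the fractions, and every value that follows describes the PY-Lo library.

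Transcripts encoded by the mitochondrial genome made up 46.5% of all PY-Lo UMIs, and the median barcode held 90.9% of its UMIs from them. At least 500 detected genes and at most 15% mitochondrially encoded UMIs left 1434 of 14377 barcodes (9.97%, interval 9.49 to 10.5), and these are called the kept cells. The mitochondrial limit alone removed 5247 barcodes, the gene limit alone 42, and both together 7654. Kept cells held 78077922 UMIs, with a median of 56294 UMIs, 8044 genes and 8.62% mitochondrial UMIs per cell. The median of non-mitochondrial UMIs was 50954 in barcodes up to 15% mitochondrial UMIs and 526.5 in those with over 50%. Whether the kept cells represent the whole PY-Lo fraction was not tested. Some 148 barcodes lay between 14 and 16% mitochondrial UMIs, close to the limit. Scrublet called 6 kept cells doublets (0.418%), and these were left in.

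**Figure D1:**
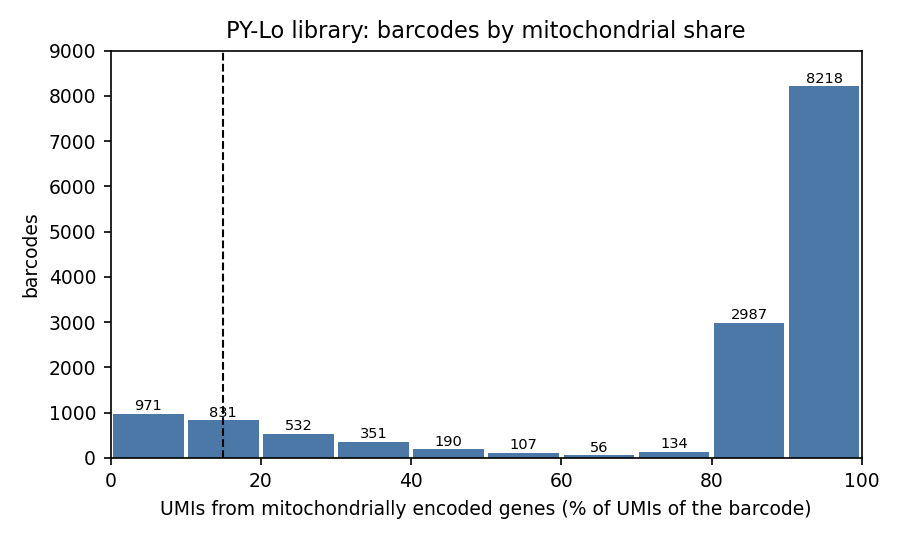
Number of PY-Lo barcodes (vertical axis) by the percent of their UMIs from mitochondrially encoded genes (horizontal axis, bins of 10 points), with the 15% limit dashed. The bins over 80% hold 2987 and 8218 barcodes, and the bins up to 20% hold 971 and 831.

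Kept cells, although sorted from the G0/G1 gate, carried transcripts of every S phase and G2/M gene listed. The 33 S phase genes took 0.451% of UMIs (interval 0.449 to 0.452), led by the histone chaperone NASP at 327 CPM (counts scaled to a common total of UMIs), the replication clamp PCNA at 287 and the thymidylate synthase gene TYMS at 281. The 36 G2/M genes took 0.342% (0.341 to 0.343), led by the chromatin protein gene HMGB2 at 527 CPM, the CDK subunit gene CKS2 at 254 and the tubulin gene TUBB4B at 231. MKI67, the gene of the proliferation antigen Ki-67, stood at 139 CPM with a UMI in 85.9% of kept cells, and in 22.6% (20.4 to 24.9) once each cell was thinned to 2000 UMIs, which 31 shallower cells could not enter. In the S100A8-high cluster of 83 cells described further on, MKI67 had 23.8 CPM and a UMI in 19.3% of cells at a median of 29051 UMIs. The replication-dependent histones stood at 712 CPM (706 to 718), of which HIST1H4C gave 567, HIST1H1C 24.9 and HIST2H2AC 24.8. Most of these mRNAs lack a poly(A) tail, so a 3' poly(A) library counts few of them.

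Of the 1298 cells that could be thinned to 20000 UMIs, every cell held S phase UMIs, with a median of 91 and a range of 1 to 165. G2/M UMIs ran from 5 to 360 with a median of 66. The 10% of cells with the most S phase UMIs held 14.1% of them, against 11.96% under counting error alone, and for G2/M these shares were 16.5% and 12.3%. Histone UMIs were less even, at 23.3% against 15.1%, and 14 cells held none.

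Genes that handle cytarabine summed to 1908 CPM (1898 to 1917), and all 17 had UMIs. DCK, the kinase that takes the first step in activating the drug, stood at 28.6 CPM (27.4 to 29.8), and SLC29A1, the main nucleoside importer, at 58.4. Among genes of drug breakdown, the cytidine deaminase gene CDA had 47.7 CPM, the deoxycytidylate deaminase gene DCTD 44.98 and SAMHD1, whose product degrades the active triphosphate, 12.9 (12.1 to 13.7). The 5'-nucleotidase genes NT5C3A and NT5C2 stood at 187 and 122 CPM. The kinase genes NME1, CMPK1 and NME2 had 306, 63.8 and 55.4 CPM. Ribonucleotide reductase was represented by RRM2 at 241, RRM1 at 223 and RRM2B at 15.7 CPM, and the polymerase gene POLA1 stood at 199. The importer genes SLC29A2 and SLC28A3 had 19.3 and 0.589 CPM. NME1 and NME2 are neighbours on chromosome 17 with similar sequences, so the split between them is uncertain.

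Of 31 gene lists, 16 reached 1000 CPM. The 10 genes with the most UMIs were MT-CO2, MT-CO3, RPS18, MT-CYB, MT-CO1, MT-ND4, MT-ATP6, the nuclear RNA MALAT1, the elongation factor gene EEF1A1 and RPS14, from 18963 down to 6495 CPM. Ribosomal protein genes took 21.4% of UMIs, with RPS18 at 12050, RPS14 at 6495 and RPS3 at 5698 CPM, and mitochondrially encoded genes 9.06%. Glycolysis genes summed to 8542 CPM (GAPDH 3983, ENO1 1089, TPI1 917), nuclear genes of oxidative phosphorylation to 5543 (CYCS 654, ATP5F1B 575, NDUFA4 514), ribosome biogenesis genes to 4338 (NPM1 1993, NCL 727, FBL 283) and heat shock genes to 2117 (HSP90AA1 1282, HSPA8 563, HSPB1 139). Genes of RNA polymerase II transcription stood at 1925 CPM (1915 to 1934), with XRN2 at 151 and MNAT1 at 138. Immediate early genes stood at 1496 (JUND 314, IER2 211, MCL1 192) and DNA damage response genes at 1432 (PARP1 201, BRCA1 166, CLSPN 148).

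Among cell cycle brakes, the quiescence and inhibitor list summed to 1189 CPM (TXNIP 433, BTG1 169, RB1 109), and G1 cyclins and kinases to 912 (CCND2 178, CDK4 173, MYC 128). CDKN2A, the p16 and p14ARF locus, had 97.4 CPM (95.3 to 99.7), and MYC, amplified in HL60, had 128 (125 to 130). The unfolded protein and integrated stress response list stood at 1395 CPM (CALR 329, HSPA5 195, TRIB3 192), the NF-kB and cytokine list at 875 (CXCL8 334, CCL4 171, CCL2 111), the BCL2 family at 817 (MCL1 192, BID 109, BAX 109) and the interferon list at 356 (BST2 156, ISG15 75.2).

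Myeloid lists dominated the cell type markers. Monocyte markers summed to 6493 CPM (6475 to 6510), of which S100A9 gave 4516, S100A8 1071 and AIF1 287. Primary granule genes stood at 1299 CPM, with SRGN at 641, CD63 at 178 and MPO, the myeloperoxidase gene, at 138. MPO had a UMI in 55.2% of cells before thinning. Late neutrophil genes reached 471 (CEBPE 222, BPI 91.7, CYBB 53.3) and stem and progenitor genes 313 (MSI2 95.1, MYB 84.9, LMO2 63.7). Lists of other lineages were low. T cell markers had 63.0 CPM, nearly all from TRAC at 54.2, with CD3D at 7.81 and CD3E at 0.589. NK cell markers had 27.7 (NKG7 26.9, KLRD1 0.525, KLRF1 0.218) and B cell markers 23.4 (PAX5 7.27, CD79A 6.81). Stromal and epithelial markers had 8.82 (KRT8 5.92, KRT18 2.43, EPCAM 0.231), megakaryocyte markers 8.45 (ITGA2B 7.71, GP1BA 0.666, PPBP 0.0768), eosinophil, basophil and mast cell markers 2.56 (PRG2 1.99, EPX 0.384, HDC 0.0768) and erythroid markers 0.730 (KLF1 0.602, ALAS2 0.102, HBG2 0.0128).

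Spread between kept cells was largest for inflammatory and myeloid genes. Excess squared coefficient of variation, the part of the squared variation beyond counting error, was highest for the metalloproteinase inhibitor gene TIMP1 (15.8), S100A8 (15.2) and S100A9 (9.62), followed by the chemokine genes CCL4 (5.45), CXCL8 (5.42) and CCL3L1 (4.65). LGALS1 (3.93), CCL2 (3.86), CCL4L2 (3.20), SH3BGRL3 (3.16), COL23A1 (2.94), MPO (2.86), NCF1 (2.34), MT2A (2.25), TYROBP (2.07), S100A4 (1.83), VPS13B (1.77), NR6A1 (1.66), TNIK (1.59) and DPYD (1.59) completed the 20 highest. Without the S100A8-high cluster described further on, TIMP1 fell to 4.01 and LGALS1 to 1.93, while S100A8 stood at 19.0 and S100A9 at 8.44. CCL4 and CCL4L2 share most of their sequence, as do CCL3 and CCL3L1, and reads could be split between copies.

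By list, 4 of 5 measured monocyte genes were variable, and their median lay at the 100th percentile of random lists matched on level. All 3 measured NF-kB and cytokine genes were variable (99.99th percentile), as were 4 of 5 stress response genes (98.7th), led by DDIT3 at 1.52 and HSPA5 at 0.781. Both MYC (0.929) and E2F3 (0.950) were variable among 4 measured G1 genes, and TXNIP (0.705) and BTG1 (0.616) among 3 quiescence genes. Of 7 measured cytarabine genes 5 were variable (96.5th percentile), led by POLA1 (1.36) and NT5C2 (0.705). S phase genes gave 12 of 21 (78.9th percentile; BRIP1 1.37, POLA1 1.36) and G2/M genes 7 of 10 (87.6th; MKI67 0.587, NUSAP1 0.489), so neither list stood far apart from random lists. Few ribosomal protein genes passed 0.25, with 4 of 78 variable (4.17th percentile; RPL22L1 0.681, RPS26 0.328), and few nuclear oxidative phosphorylation genes, with 2 of 17 (2.97th; UQCRQ 0.501, ATP5MC1 0.321). These lists still differed between cells, as they were 9.29-fold and 4.26-fold lower in cluster 5, described further on. Random lists could also draw members of the list itself, which matters most for the 78 ribosomal protein genes. In all, 724 of 1664 measured genes (43.5%) passed 0.25, where counting error alone gave 59 of 1688. Another random thinning called 731 genes, of which 482 were among the 724, so single genes near 0.25 are uncertain. VPS13B, NR6A1 and TNIK fell to 0.906, 0.949 and 0.605 with it, and without the low ribosomal protein cluster described further on the number was 412.

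**Figure D2:**
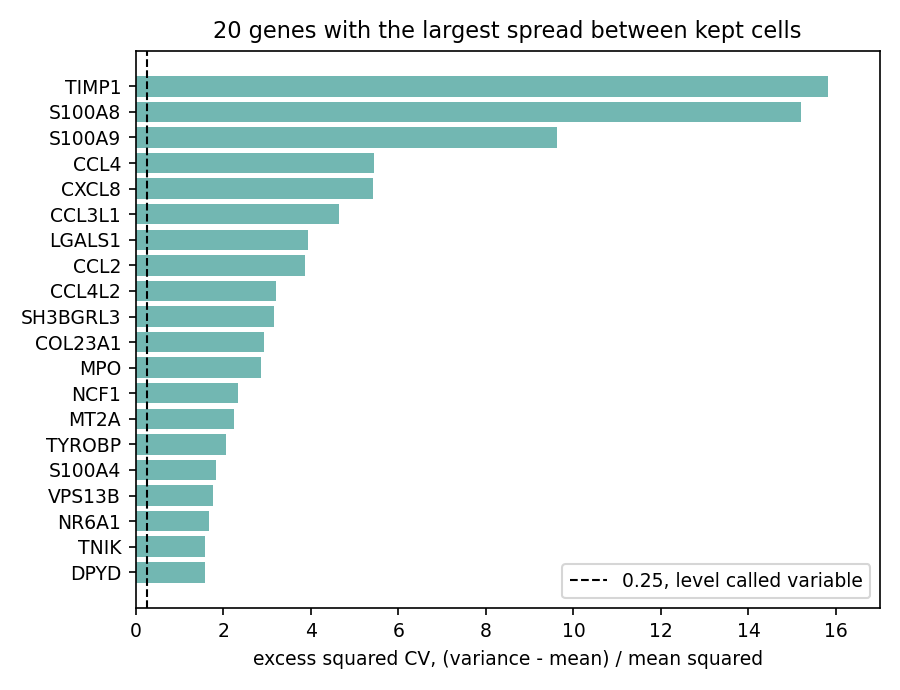
Excess squared coefficient of variation (horizontal axis, no unit) of the 20 most variable genes (vertical axis) over 1403 kept cells thinned to 2000 UMIs. Bars run from 1.59 for DPYD to 15.8 for TIMP1, and the dashed line marks 0.25.

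Because Pyronin Y reads RNA content, kept cells were also compared by total UMIs, the nearest measure in the counts, which capture efficiency also sets. The 25% of cells with the most UMIs (351 cells, median 79982) are called UMI-rich and the 25% with the fewest (351 cells, median 25337) UMI-poor, all thinned to 2000 UMIs. Of the 12 genes highest in UMI-rich cells, the cell cycle and histone lists hold HIST1H4C, UBE2C and TYMS. HIST1H4C was 1.63 higher on the log2 scale (interval 1.35 to 1.91), the ubiquitin-conjugating enzyme gene UBE2C 1.37 (0.94 to 1.81), TYMS 1.31 (0.95 to 1.67), PEBP1 1.26, the telomerase cofactor gene DKC1 1.10, SIVA1 1.09, CKS1B 1.07, MPC2 1.06, DUT 1.05, HMGN2 1.05, IMPDH2 1.05 and the PCNA-associated gene PCLAF 1.03. UMI-poor cells had more of the calprotectin genes. S100A8 had a log2 ratio of UMI-rich over UMI-poor of -3.16 (-3.35 to -2.98), S100A9 -2.56, TIMP1 -2.04, LGALS1 -1.87, MBD5 -1.67, DPYD -1.41, SH3BGRL3 -1.38, VPS13B -1.37, LRMDA -1.31, ATG7 -1.29, GBE1 -1.22 and SMYD3 -1.22. Several of these rest on the small clusters described further on. Without the S100A8-high cluster SH3BGRL3 stood at 0.0125 and TIMP1 at 0.0766. Without it and the low ribosomal protein cluster MBD5 stood at 0.73, VPS13B at 0.38, SMYD3 at 0.33 and LRMDA at 0.13, and among the genes listed as higher SIVA1 stood at -0.0426 and MPC2 at -0.18. In GRCh38, S100A8 (ENSG00000143546) and S100A9 (ENSG00000163220) lie on chromosome 1 at 153390032 to 153391188 and 153357854 to 153361027. HIST1H4C (ENSG00000197061) lies on chromosome 6 at 26103876 to 26104310 and TYMS (ENSG00000176890) on chromosome 18 at 657604 to 673578.

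All 6 measured G2/M genes were at least 1.5-fold higher in UMI-rich cells (median log2 0.75, 99.9th percentile), from TOP2A at 0.63 to UBE2C. Of 12 S phase genes 3 were higher and 1, POLA1 at -0.93, was lower (median 0.46, 98.4th percentile). Oxidative phosphorylation genes gave 6 of 14 higher (median 0.52, 98.6th percentile), from COX6C at 0.22 to CYCS at 0.87, and ribosome biogenesis genes 3 of 7, from NOP58 at -0.44 to DKC1. Of 78 ribosomal protein genes 8 were higher, led by RPS20 at 0.91, and RPL36 was lowest at 0.11. Of 7 cytarabine genes TYMS was highest and NT5C2 lowest at -1.12, with 2 higher and 2 lower. Among 3 RNA polymerase II genes 2 were lower, with XRN2 highest at -0.11. The monocyte list summed to -2.40 (-2.46 to -2.34, 0.02nd percentile for its median), with AIF1 at 0.55. Single members past 1.5-fold stood in other lists, namely CDK4 at 0.61, BTG1 at 0.75, PARP1 at 0.62, IER2 at 0.64, HSP90AA1 at 0.69, CEBPE at 0.58, MSI2 at -0.85 and MT-ATP8 at -0.63. Among 1068 measured genes 173 were at least 1.5-fold higher and 197 lower, and the median gene lay at 0.18. Of the UMI-poor cells 106 belonged to the low ribosomal protein cluster and 67 to the S100A8-high cluster. In the low ribosomal protein cluster, ribosomal protein genes were 9.29-fold, oxidative phosphorylation genes 4.26-fold and ribosome biogenesis genes 2.19-fold lower than in other kept cells. The ratios of these lists without this cluster are not given here. Their higher levels in UMI-rich cells are thus not separated in this text from this cluster's share of UMI-poor cells. Leaving out the low ribosomal protein cluster left 28 genes higher and 19 lower. Leaving out both clusters left 10 and 4, with S100A8 at -1.57 and the G2/M list at 0.19 against 0.65.

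**Figure D3:**
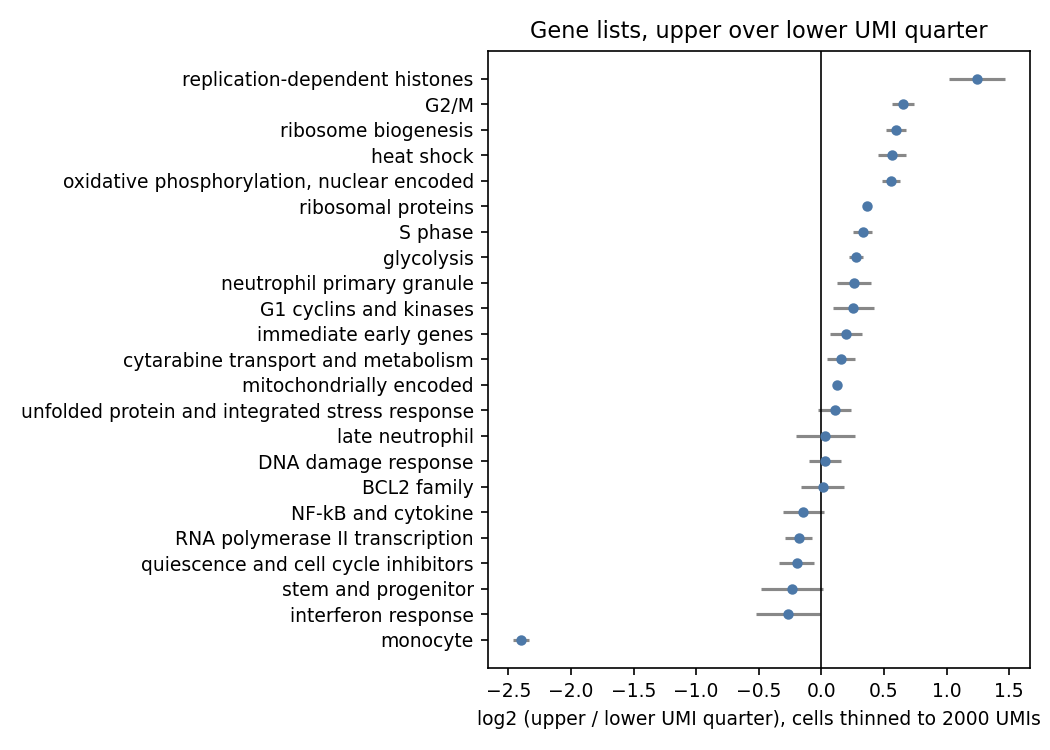
Log2 ratio of summed thinned counts, the 25% of kept cells with the most UMIs over the 25% with the fewest (horizontal axis), for gene lists of at least 200 CPM in both groups (vertical axis). Points are the ratios and lines the exact 95% counting intervals, from -2.40 for the monocyte list to 1.24 for replication-dependent histones.

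Clustering split the kept cells into 7 groups. Folds of leading genes have 10 CPM added to both sides, and other folds are plain ratios. Cluster 7 (83 cells, 5.79%, interval 4.64 to 7.12) held 4 of the fixed monocyte markers among its 10 leading genes, S100A12, S100A8, S100A9 and FCER1G, which neutrophils also express. The monocyte markers CD14 and CSF1R stood at 7.67 and 1.53 CPM there and the neutrophil receptor gene CSF3R at 176, so the cluster was given no cell type name. It was led by S100A12, S100A8, S100A9, HPGD, TIMP1 and NAV3, at 30.5, 19.8, 16.4, 13.0, 11.1 and 10.5 times the level of other cells. In it the S phase list was 4.89-fold and the G2/M list 2.98-fold lower than in other cells, and they were 4.88-fold and 2.96-fold lower in the matching cluster of 81 cells found with the cell cycle genes left out of the clustering. MPO stood at 2.30 CPM in cluster 7 against 143 in other cells, and MYC at 31.8 against 131. The primary granule list as a whole was 1.37-fold and the late neutrophil list 1.51-fold higher there. The NF-kB list was 2.20-fold and the interferon list 2.12-fold higher. Cluster 5 (113 cells, 7.88%) was led by MIR181A1HG, KCNQ5, MIR99AHG, CCDC26, SCFD2 and ALOX12-AS1, at 4.90 to 5.72 times other cells. KCNQ5 and CCDC26 are long genes, and whether intronic reads were counted is not given in the sources used here. Ribosomal protein genes were 9.29-fold lower there, glycolysis genes 5.05-fold and oxidative phosphorylation genes 4.26-fold, and its median was 18797 UMIs.

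Cluster 1 (380 cells, 26.5%) was led by ATF5, TRIB3, ORM1, C6orf48 and DDIT3 (2.79 to 2.21 times other cells), among which ATF5, TRIB3 and DDIT3 are known targets of the integrated stress response. Cluster 2 (375 cells, 26.2%) was led by ID3, HSPE1, DBI, TUBB4B, FABP5 and PRDX1 (2.00 to 1.73). Cluster 3 (262 cells, 18.3%) was led by the sterol synthesis gene HMGCS1, CEACAM6, DACH1, TBC1D4, the sterol sensor gene INSIG1 and GPR135 (1.94 to 1.69). Cluster 4 (121 cells, 8.44%) was led by CCL3L1, the CDK inhibitor gene CDKN1A, CCL4, EGR1, the haem oxygenase gene HMOX1 and CCL4L2 (3.55 to 2.41). Its NF-kB list was 1.95-fold and its immediate early list 1.46-fold higher than in other cells, while the monocyte list was 3.84-fold lower. The other cells include cluster 7, where the monocyte list stood at 65194 CPM. This list was also lower in clusters 1 (3.27-fold), 2, 5 (12.3-fold) and 6, and higher only in clusters 3 and 7. Cluster 6 (100 cells, 6.97%) was led by RPL22L1, ORM1, SNHG15, U2AF1L4, RBCK1 and EIF4EBP1 (2.10 to 1.76). With the barcode filter in place, clusters 5 and 7 held together best across settings, with shares of cells in common of at least 0.566 and 0.627, while the others fell to between 0.189 and 0.401 in at least 1 setting. Cells that a stricter filter removed count as not shared. The lowest shares of clusters 1, 3, 5 and 7 came with the limit of 10% mitochondrial UMIs. There, all 64 cells of the group matched to cluster 5 belonged to it, so these shares partly reflect removed cells. Without a barcode filter clusters 5 and 7 were lost among other barcodes, at 0.0842 and 0.0500, and the highest share was 0.239 for cluster 1.

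**Figure D4:**
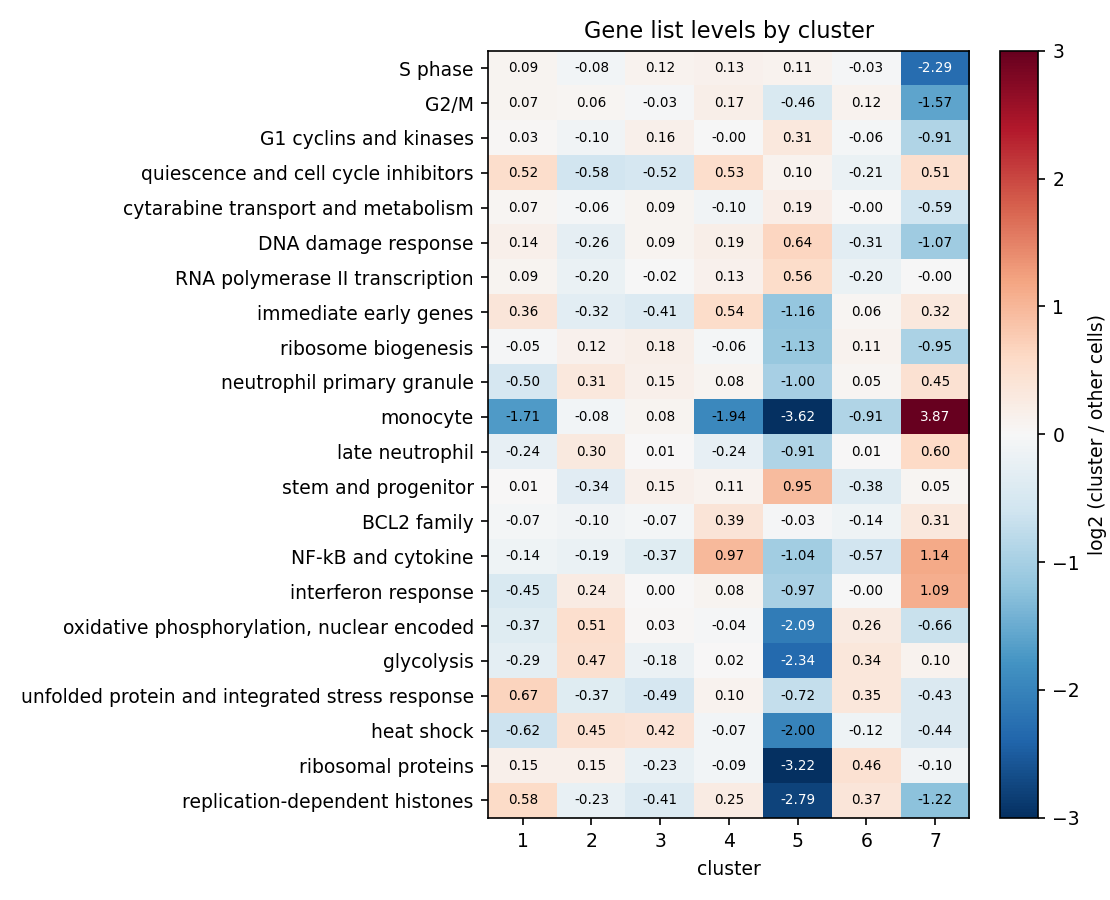
Log2 ratio of gene lists (rows) in each of the 7 clusters (columns) over all other kept cells, with colours limited to -3 to 3. The monocyte list reads 3.87 in cluster 7 and the ribosomal protein list -3.22 in cluster 5.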

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

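Of the tests in this part, the alignment to mitochondrial transcripts was set before its result was seen, and the others, with the ranges and the list of nuclear-retained RNAs, were chosen afterwards. Signals stood in barcodes that no comparison used. Barcodes with over 50% mitochondrially encoded UMIs numbered 11502 (80%, interval 79.3 to 80.7), with a median of 6531 UMIs, of which 526.5 were not mitochondrial. Another 1399 barcodes lay between 15 and 50%, with a median of 15030 UMIs that were not mitochondrial. Of the PY-Lo barcodes, 59 also occur in the PY-Hi list. They had a median of 6999 UMIs and 90.7% mitochondrial UMIs, against 7262.5 and 90.9% for other barcodes, and 10.2% of them were kept against 9.97%. By these measures they did not stand apart, and the number that both lists would share by chance was not computed.

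In barcodes with 15 to 50% mitochondrial UMIs, genes were compared with barcodes up to 15% as shares of the non-mitochondrial UMIs. The nuclear RNAs MALAT1 and NEAT1 were 1.08 and 1.13 higher on the log2 scale, CCDC26 1.68 and KCNQ5 1.73, while ribosomal protein genes had -1.24, glycolysis genes -1.06 and HIST1H4C -1.57. The list of nuclear-retained RNAs was 1.25 higher, above all but a negligible part of matched random lists (100th percentile), which is consistent with lost cytoplasmic RNA around a kept nucleus. Part of that list was picked after its genes were seen in these cells, so MALAT1 and NEAT1 are the firmer members.

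Barcodes with over 50% differed otherwise. Their mitochondrial share varied 14.1 times as much as counting error allows, which argues against 1 uniform mixture of free RNA in all of these droplets. The nuclear-retained list stood at -0.065 in sum and 0.43 in its median, MALAT1 at -0.29 and NEAT1 at -0.44, so loss of the cytoplasm with the nucleus kept cannot be told apart from other sources there. The MTRNR2L genes, whose sequences copy mitochondrial ribosomal RNA, were 250-fold higher, AC105402.3 109-fold, GPM6A 38.0-fold, TCHH 13.8-fold and LINC00486 13.0-fold. With the MTRNR2L genes set aside, 0 of the 15 highest genes in these barcodes had a transcript that aligned to a mitochondrial transcript over 50 bases, but introns were not searched, so mitochondrial reads assigned to them stay open, as does low RNA content picked by the Pyronin Y gate, which was not tested.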

How the results depend on the processing

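No paired analysis was possible because the PY-Hi counts were not analysed here, and no value has a replicate. The number of lists over 1000 CPM stayed within 1.5 times under all 7 alternatives, and requiring 1000 genes or leaving out doublets moved no count past 1.5 times. Without the doublets 475 of 719 variable, 118 of 192 higher and 150 of 199 lower genes were among the first calls. Leaving out cells also redraws the thinning of cells that follow them. Another random thinning alone kept 482 of 731 variable genes, so this overlap does not show an effect of the doublets. Leaving out clusters and thinning to 20000 UMIs were chosen after seeing the data. Without a barcode filter 14377 barcodes stayed, the S phase share was 0.270% and G2/M 0.187%, MKI67 was found in 5.34% of thinned barcodes, 209 genes were variable, and by total UMIs 5833 were higher and 17 lower of 5851 measured genes. Mitochondrial UMIs then made up 46.5%, which lowers the share of all other genes. Of non-mitochondrial UMIs, S phase genes held 5272 CPM in barcodes with 15 to 50%, 5347 with over 50% and 4960 up to 15%. G2/M genes held 2849, 3516 and 3762. As nearly all measured genes were higher, a turned sign was not particular to a gene. The signs then turned for SMYD3 (3.40), GBE1 (2.89), ATG7 (2.78), LRMDA (3.62), VPS13B (3.09), SH3BGRL3 (2.77), DPYD (3.58), MBD5 (3.22), LGALS1 (3.08), TIMP1 (2.97), S100A9 (3.11), S100A8 (3.10) and the monocyte list (2.99). At most 10% mitochondrial UMIs gave 949 cells, 0.455% S phase, 0.349% G2/M, and 119 higher and 78 lower of 549 measured genes. Without the low ribosomal protein cluster G2/M was 0.345%, with 412 variable, 28 higher and 19 lower genes. Without the S100A8-high cluster SH3BGRL3 was at 0.0125 and TIMP1 at 0.0766, and without both clusters there were 350 variable, 10 higher and 4 lower genes, SIVA1 was at -0.0426, MPC2 -0.18, SMYD3 0.33, LRMDA 0.13, VPS13B 0.38 and MBD5 0.73. Thinning to 1000, 3000 and 20000 UMIs found MKI67 in 11.0, 30.3 and 83.1% of cells and 220, 1299 and 3998 variable genes. Higher genes were 87 and 297 at 1000 and 3000, and lower genes 45, 432 and 403 at the 3 depths. Floors of 0.1 and 0.5 gave 1875 and 128 variable genes. Depth and floor set how many genes are measured for spread (600, 2829 and 9017 at these depths), so the variable counts move by construction. Thinning to 20000 also left out 136 cells, so its counts mix both changes, and only 45 of its 223 higher and 40 of its 403 lower genes were among the first calls. The upper and lower 10% of cells gave 147 higher and 41 lower of 248 measured genes. The limit of 10% mitochondrial UMIs and the upper and lower 10% use fewer cells, so fewer genes passed the floor than the 1068 of the main setting. Resolution 1.0 gave 12 clusters. For the other changes the cause was not tested. Depth limits single genes to those with about 100 CPM or more after thinning.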

Other observations

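Cluster 7 differed from other cells in further genes. CCDC26, a long non-coding RNA gene on chromosome 8 near MYC in a region amplified in HL60, stood at 3412 CPM there against 2666 in other cells. CCDC26 was also high in cluster 5. In barcodes with over 50% mitochondrial UMIs it stood at 3980 CPM of the non-mitochondrial UMIs. Its level therefore does not show the origin of cluster 7, and no copy number was measured. In cluster 7 IL1B was 138-fold higher (60.2 against 0.437 CPM), LYZ 10.3-fold, CYBB 4.28-fold and CSF3R 4.09-fold, while MPO was 62.2-fold lower, RRM2 10.6-fold, TYMS 7.87-fold and MYC 4.11-fold. Cluster 5 resembled the barcodes with 15 to 50% mitochondrial UMIs, with MALAT1 at 26335 against 7216 CPM and CCDC26 at 12132 against 2399.

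The tests of S phase and G2/M transcripts in G0/G1-gated cells were chosen after the result was seen, and the tests of the genes that differed with total UMIs before. S phase transcripts were found in all 1298 cells thinned to 20000 UMIs. The 10% of cells with the most held 14.1% of them, which argues against a minority of replicating cells that passed the gate as the whole source. This share cannot tell whether such a minority added to them, since other cells also held these transcripts. In 1 of 7 clusters formed without cell cycle genes, with 81 cells, the S phase list fell to a log2 ratio of -2.29 (949 against 4629 CPM), while the other 6 lay between -0.09 and 0.12, and free RNA spread alike over all cells would not leave 1 cluster so low. Without the 6 called doublets the share was 0.451%, but 6 cells are too few for this to say whether doublets added to it. A hypothesis left open is that cytarabine may hold cells at the start of S phase, with a DNA content near that of G1, which untreated cells would be needed to test.

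For the genes that differed with total UMIs, S100A8 was still at -0.82 (-1.04 to -0.59) without the S100A8-high cluster. The interval passed the 1.5-fold bound set beforehand only narrowly, and it covers counting error only. The excess squared coefficient of variation of S100A8 between cells was 19.0 without that cluster, a spread the interval leaves out. Whether that cluster is the whole source can therefore not be told. The G2/M list was at 0.19 (0.10 to 0.28) without both small clusters, against 0.65, and its interval includes the bound of 0.2 set beforehand, so whether these clusters may account for it cannot be told apart from a remaining difference. No biological explanation was tested.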
